A study of Homo sapiens with 8 samples.

How the data were processed

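RNA of 8 samples of Ishikawa cells was sequenced from stranded mRNA libraries, per the labels' protocols, after growth in phenol red-free medium with charcoal-stripped serum, which removes steroid hormones. The labels of the samples give a treatment time of 8 hr, whereas the treatment protocol shared by all samples gives 1 hr. The sample labels are used here, and which of these times applies to the RNA is not settled by the sources used here.

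The authors deposited a table of raw counts per gene and a table of normalised values for the same 8 libraries. Per the submitters' processing notes, the tools were HISAT2 2.0.4, Subread with featureCounts 1.5.1 and DESeq2 1.14.1, with the human build hg19. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may not be separated. The deposited counts are whole numbers. In the deposited normalised table each value is a signal equal to the raw count divided by a single factor per library, between 0.876 and 1.11, to within a relative deviation of 5.1e-15. The normalised table was used only for that check, and the counts for all tests. Genes are identified by symbol as in the table. No coordinates are given, because the reference annotation used here is of another build.

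Each column was assigned to a group and replicate by its name. Both combination columns carry the number 1. The column whose name matches the label of combination replicate 1 was taken as that sample, and the other as a combination library without a number. Library totals were between 17846211 and 22487333 counts. Values of genes with few counts are imprecise at this depth: KDR at 0.180 CPM in DMSO rests on 5 and 2 counts.

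Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the raw counts. Genes were filtered with filterByExpr by group, which left 14201 of 26364, scaled by the TMM method, and fitted with the quasi-likelihood model (glmQLFit, glmQLFTest) with all 8 libraries and 4 groups in the same fit, which leaves 4 residual degrees of freedom. The 6 contrasts were dexamethasone, estradiol and the combination against DMSO, the combination against each single hormone, and the interaction, which is the dexamethasone effect with estradiol minus that without it. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Standard errors were derived from the fold change and the test statistic. Printed CPM values are counts scaled to the TMM-scaled library size.

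Gene groups were 30 lists fixed before the data were examined, of which 26 had at least 5 tested members. They covered targets and cofactors of both receptors, endometrial, cell cycle, metabolic and signalling genes, housekeeping genes, signs of library quality and markers of other cell types. Mitochondrially encoded mRNAs had 0 genes in the table. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. Fry tests whether the genes of a list move, on balance, in the same direction, without comparing them with other genes. The counts of called members were also computed with adjustment over the list alone.

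The genes named in the text follow a rule fixed at the same time. Per contrast it takes the 8 genes with the largest positive and negative log2 fold changes among those called, with a mean log2 CPM above 1 and no overlap between the libraries of both groups. It adds up to 4 members with the smallest p of each list, and ESR1, NR3C1, PGR, FKBP5, TSC22D3, PER1, GREB1, TFF1 and PDZK1. Some genes that the rule takes are not reported here. RNA45S5 was singled out after its values were seen, and so was dexamethasone replicate 1 as a library that stands apart.

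The tests were tested on simulated data drawn with the DMSO means, library sizes and dispersions of these libraries, with 50, 50 and 100 genes changed by 1.5, 2 and 4 fold. The changed genes were taken only from those with a DMSO mean above 2 CPM, so the shares recovered do not cover genes below that. For the dexamethasone contrast, over 13919 simulated genes, 60% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes were recovered, with 8 false calls among 182. For estradiol, over 13917 genes, these were 50%, 90% and 100%, with 10 false calls among 180. For the interaction, over 13925 genes, they were 12%, 78% and 100%, with 7 false calls among 152. Of the recovered genes 0 had the wrong direction. For the dexamethasone contrast, 0.2% of 500 random lists of 20 unchanged genes had a camera p under 0.05. The genes were simulated independently of one another, so this rate says nothing about lists whose genes vary together. In the real data the estimated correlation for dexamethasone was 0.299 in the ribosome biogenesis list and 0.563 in the histone list.

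Transcripts of the named genes were searched with blastn 2.17.0+ against GENCODE transcripts for copies of at least 95% identity over 200 bases, for 98 of 102 genes. Such copies were found for POTEF, LEFTY1, LEFTY2, PDZK1, BNIP3, MT1X, IQSEC3, GREB1, NR3C1, OSGIN1 and TGFB2, whose counts are uncertain to the extent that reads fall in the shared stretches. For GREB1 this was 233 bases.

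Alternatives fixed beforehand were DESeq2 1.42.0 and limma-voom in place of edgeR, size factors in the style of DESeq2 or library totals in place of TMM, no filter or a mean count of at least 50, an adjusted p under 0.01, an absolute log2 fold change of at least 1, only the libraries of the groups compared, the replicate number as a block, which was then fitted to the 6 numbered libraries, and each library left out in turn. In the last case the remaining library of a group is assumed to vary like the other groups. Added after seeing the data were a fit of the 6 numbered libraries, a block of all 8 libraries with the second combination column as replicate 2, a fit without RNA45S5, and list tests without dexamethasone replicate 1. For contrasts that share the DMSO libraries, 20 sets of unchanged groups were simulated, with the DMSO group drawn anew in each.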

Results

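Gene expression was measured by RNA sequencing in Ishikawa cells, an established line of human endometrial adenocarcinoma that responds to estrogen. The cells received vehicle (DMSO), dexamethasone at 100 nM (a synthetic agonist of the glucocorticoid receptor), estradiol at 10 nM (an agonist of the estrogen receptor), or both hormones together. Each of the 4 groups had 2 libraries, 8 in all. The libraries held between 17846211 and 22487333 counts assigned to genes, and between 16969 and 17507 genes had at least 1 count in a library. Of 26364 genes in the count table, 14201 passed the expression filter and were tested. Levels are given as CPM, which are counts scaled to the size of the library, as the mean ± SD of the 2 libraries of a group (n = 2). Log2 fold changes are given ± the standard error of the fit, and a gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

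The libraries of a group differed by more than sampling noise in every group, with a chi-square per degree of freedom of 17.2 in DMSO, 24.8 in dexamethasone, 9.61 in estradiol and 12.2 in the combination. Dexamethasone replicate 1 stood apart from replicate 2 at genes that estradiol raises. PGR was at 8.91 CPM in replicate 1 and 2.47 CPM in replicate 2, GREB1 at 17.7 and 6.85 CPM, and THBS1 at 356 and 112 CPM. The corresponding DMSO libraries had 4.09 and 2.53 CPM of PGR and 8.03 and 6.71 CPM of GREB1. The ribosomal RNA gene RNA45S5 took 1.42% of the counts in dexamethasone replicate 2 and between 2.79% and 4.03% in the other libraries. Leukocyte marker genes reached at most 1.77 CPM (CD68), endothelial markers 7.77 CPM (ESAM) and fibroblast markers 185 CPM (COL1A1). COL1A1 was at 164 ± 30.4 CPM in DMSO and 131 ± 12.1 CPM in the combination, and was called in no comparison.

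The first comparison asked which genes respond to dexamethasone alone. Dexamethasone raised known glucocorticoid-induced genes. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, rose from 14.3 ± 1.76 to 134 ± 21.3 CPM, a log2 fold change of 3.23 ± 0.14. PER1, a repressor of the circadian clock, rose from 19.0 ± 1.01 to 127 ± 2.49 CPM, and FKBP5, a co-chaperone that restrains the glucocorticoid receptor, rose from 88.4 ± 5.10 to 281 ± 31.0 CPM. The largest increases among well-expressed genes were those of STAC2 (log2 fold change 3.54 ± 0.19), LEFTY1, an antagonist of Nodal signalling (3.39 ± 0.38), and PPP1R1B, an inhibitor of protein phosphatase 1 (3.14 ± 0.14). GMPR rose by 2.68 ± 0.21 and RASSF4 by 2.57 ± 0.25. LEFTY1 shares 1203 bases at 96.4% identity with LEFTY2, so its counts are uncertain where reads fall in that stretch.

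Of 14201 genes, 137 changed with dexamethasone, 129 upward and 8 downward, while 1398 genes had an unadjusted p under 0.05. Among the genes that fell, the clock repressor NR1D2 dropped by 0.92 and the cytokine signalling inhibitor SOCS2 dropped by 0.98 on the log2 scale. POTEF, an actin-related gene of the POTE family, was the most strongly lowered, from 87.8 ± 16.9 to 1.09 ± 0.43 CPM. It shares long stretches with its paralogs and with ACTB, so its counts are uncertain. The 8 genes with the largest increases kept their call without each of the 8 libraries in turn, as did POTEF and NR1D2 among those that fell. FAM46C, DMBX1 and FRMD6, which also fell, lost it without some of the libraries, and OSGIN1 and MGEA5 without each of them. SOCS2 lost its call without DMSO replicate 1 or either dexamethasone library (adjusted p up to 0.0635). Without DMSO replicate 1 the number of changed genes was 78. Without dexamethasone replicate 1, the library with the higher estrogen-induced genes, it was 100 (89 higher and 11 lower), of which 83 were among the 137. With only the 4 libraries of both groups in the fit it was 63.

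Of 43 tested glucocorticoid target genes fixed in advance, 15 rose and 0 fell with dexamethasone, or 22 and 2 when adjusted over the list alone, and DESeq2 called 16 of them. Beside TSC22D3, PER1 and FKBP5, SCNN1A, the alpha subunit of the epithelial sodium channel, rose by 2.02 ± 0.09 on the log2 scale. The list as a whole stood above other genes (camera, adjusted p = 5.78e-56, and adjusted p = 0.00796 with an estimated correlation). Ion and water transport genes also ranked higher, with 2 of 14 called, SCNN1A among them, or 4 higher and 1 lower adjusted over the list alone. Their adjusted p was 1.5e-07, and 0.0484 with an estimated correlation, but without dexamethasone replicate 1 the latter was 0.262. Of the inflammatory NF-kB targets, 1 of 12 changed, also when adjusted over the list alone. It was NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, which rose from 49.9 ± 2.33 to 110 ± 5.35 CPM. The list itself did not pass (adjusted p = 0.0559). Among 4 tested metallothioneins MT1X rose by 0.94 ± 0.19, a call lost without DMSO replicate 1, dexamethasone replicate 2 or either estradiol library (adjusted p up to 0.284). KDR, a receptor for vascular growth factor on the endothelial marker list, rose from 0.180 ± 0.117 to 1.38 ± 0.11 CPM (log2 fold change 2.92 ± 0.45). It had 5 and 2 counts in the DMSO libraries, and the call was lost without DMSO replicate 2 (adjusted p = 0.0883).

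Of 42 estrogen targets 0 were called with dexamethasone by edgeR, while 15 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0, and 5 passed when adjusted over the list alone. The list ranked higher in the camera test (adjusted p = 0.00151). It did not pass with an estimated correlation (adjusted p = 0.38) or without dexamethasone replicate 1 (adjusted p = 0.268), the library in which estrogen-induced genes stood higher. The mesenchymal and actin list (adjusted p = 0.00154, and 0.413 with an estimated correlation) ranked higher with 0 of 22 called by edgeR, DESeq2 or limma-voom, 8 at an unadjusted p under 0.05 and 4 adjusted over the list alone. The epithelial receptivity list (0.0232, then 0.38 with an estimated correlation, and 0.0942 without dexamethasone replicate 1) had 0 of 10 called by each tool, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The circadian clock list (0.0075, and 0.38 with an estimated correlation) had PER1 higher and NR1D2 lower, or 2 and 1 adjusted over the list alone. The decidualization (0.00822), epithelial junction (0.0197) and glycolysis and hypoxia (0.0437) lists, with adjusted p-values of 0.38, 0.413 and 0.536 with an estimated correlation, each had 1 member called, LEFTY2, KRT23 and BNIP3. Adjusted over the list alone these were 2 higher, 6 higher and 1 lower, and 1 higher. LEFTY2 lost its call without each of the 8 libraries (adjusted p up to 0.302), KRT23 without DMSO replicate 1 or any dexamethasone or estradiol library (up to 0.208), and BNIP3 without dexamethasone replicate 1 or any DMSO or combination library (up to 0.139).

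**Figure D1:**
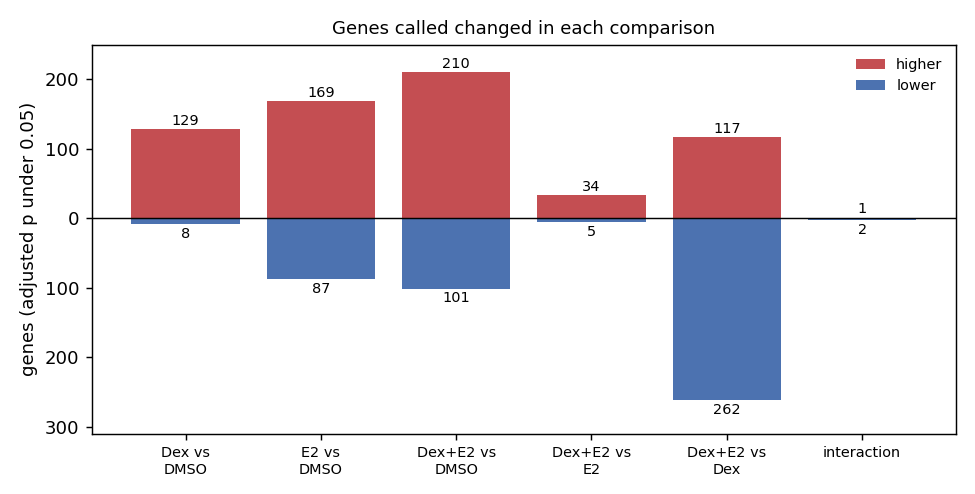
Number of genes called higher (red, above 0) or lower (blue, below 0) in each comparison, at an adjusted p under 0.05 among 14201 genes. The estradiol effect in the presence of dexamethasone had the most calls (117 higher and 262 lower) and the interaction the fewest (1 and 2).

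The second comparison asked which genes respond to estradiol alone. Estradiol raised PGR, the progesterone receptor gene and a classical estrogen target, from 3.31 ± 1.11 to 36.4 ± 6.55 CPM (log2 fold change 3.46 ± 0.40). ALPI, an alkaline phosphatase, rose by 4.43 ± 0.41, the RNA-binding protein gene RBM24 by 4.30 ± 0.38, NPPC, which encodes C-type natriuretic peptide, by 4.06 ± 0.37, and the retinaldehyde reductase gene DHRS3 by 4.01 ± 0.49. GREB1, an estrogen-induced growth regulator, rose by 1.98 ± 0.31 on the log2 scale. In the other direction CYP1A1, a cytochrome P450 that hydroxylates estrogens, fell from 12.3 ± 3.33 to 2.79 ± 0.76 CPM, and BMF, a promoter of apoptosis, fell from 22.7 ± 2.92 to 6.34 ± 0.91 CPM.

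In total 256 genes changed with estradiol, 169 upward and 87 downward, and 1619 had an unadjusted p under 0.05. DDIT4, an inhibitor of mTORC1 that glucocorticoids induce, fell by 1.22 on the log2 scale, and POTEF fell by 5.56. CYP1A1 lost its call without estradiol replicate 2 (adjusted p = 0.106). The gene of estrogen receptor alpha, ESR1, fell from 169 ± 17.0 to 123 ± 2.58 CPM (log2 fold change -0.46 ± 0.10, adjusted p = 0.0472). This call was lost without DMSO replicate 1, either estradiol library or either combination library (adjusted p up to 0.304). NR3C1, the glucocorticoid receptor gene, was at 64.9 ± 2.13 CPM in DMSO and 61.9 ± 5.09 CPM with estradiol, and was called in no comparison. The number of changed genes depended on single libraries: it was 58 without estradiol replicate 2, 87 without estradiol replicate 1 and 131 without DMSO replicate 2. GREB1 lost its call without either estradiol library (adjusted p up to 0.123). Without dexamethasone replicate 1, which is in neither group of this comparison, 298 genes changed.

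Of 42 estrogen targets, 17 rose and 1 fell with estradiol, or 20 and 3 when adjusted over the list alone. They included CA12, a carbonic anhydrase (2.65 ± 0.25), and the lipid transporter gene ABCA3 (0.79 ± 0.10). The list ranked far above other genes (adjusted p = 1.08e-23), with an adjusted p of 0.093 with an estimated correlation. Of 43 glucocorticoid targets, 3 rose and 2 fell, or 5 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.448). CEBPB, a transcription factor gene, rose by 0.84 ± 0.10 and TFCP2L1 by 1.20 ± 0.19, while CRISPLD2 fell by 0.82 on the log2 scale. TFCP2L1 lost its call without either estradiol library (adjusted p up to 0.109) and CRISPLD2 without replicate 2 (0.0612). Ribosome biogenesis genes ranked higher as a group (median log2 fold change 0.28, adjusted p = 5.19e-08) although edgeR and limma-voom called 0 of 25, 12 had an unadjusted p under 0.05, DESeq2 called 2 and 9 were higher adjusted over the list alone. With an estimated correlation their adjusted p was 0.448. Ion and water transport genes ranked higher (adjusted p = 1.65e-05, and 0.093 with an estimated correlation), with CA12, CA2 and the scaffold gene SLC9A3R1 higher, also when adjusted over the list alone. The glycolysis and hypoxia list (adjusted p = 0.0299) and the Wnt list (0.0413) also ranked higher, while the apoptosis list (0.0299) and the epithelial junction list (0.0412) ranked lower. With an estimated correlation these 4 lists had adjusted p-values of 0.448 to 0.583. Of the 23 glycolysis and hypoxia genes 2 rose, VEGFA (0.70 ± 0.10) and BNIP3, and of the 13 Wnt genes 2 rose, WNT11 (2.14 ± 0.36) and FZD5 (0.83 ± 0.15), 3 in each adjusted over the list alone. Of the 16 apoptosis genes BMF and the death receptor gene FAS fell, or 1 rose and 4 fell adjusted over the list alone, and of the 19 junction genes JUP fell, or 2 fell. Without either estradiol library VEGFA (adjusted p up to 0.0865), WNT11 (0.153), FZD5 (0.179), FAS (0.249) and JUP (0.299) lost their calls, and without DMSO replicate 2 so did WNT11, FZD5, FAS and JUP. BNIP3 was lost without any of the DMSO or estradiol libraries (up to 0.16), FAS also without DMSO replicate 1, and FAS and JUP without either combination library.

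**Figure D2:**
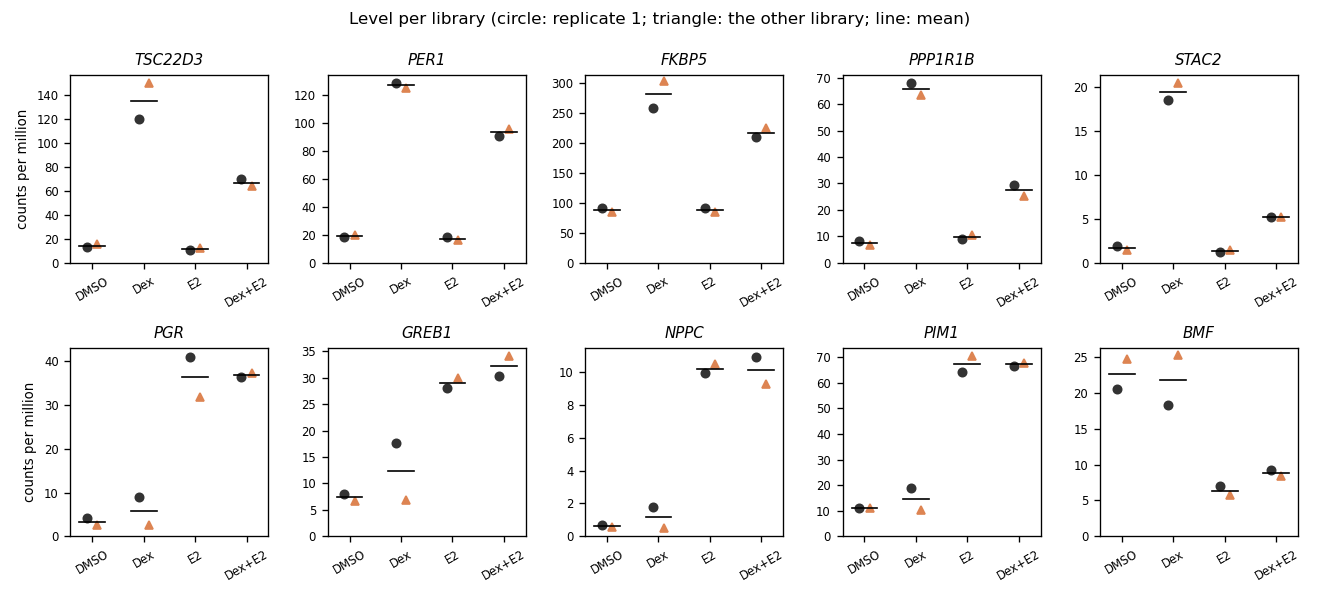
CPM of 10 genes in each of the 8 libraries, by treatment, with circles for replicate 1, triangles for the other library of the group and lines for the mean of both. TSC22D3, PER1, FKBP5, PPP1R1B and STAC2 are higher with dexamethasone, at 134 CPM for TSC22D3 alone and 66.8 CPM with estradiol, while PGR, GREB1, NPPC and PIM1 are higher with estradiol, and BMF is lower.

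The third comparison set cells given both hormones against vehicle. The combination raised genes of both single responses. PGR reached 36.9 ± 0.59 CPM and GREB1 32.2 ± 2.73 CPM, close to their levels with estradiol alone. TSC22D3 reached 66.8 ± 4.63 CPM (log2 fold change 2.22 ± 0.14) and PER1 93.1 ± 3.57 CPM, and FKBP5 rose by 1.29 ± 0.11 on the log2 scale. ALPI, NPPC and DHRS3 rose by between 3.98 and 4.21 on the log2 scale. G0S2, an inhibitor of triglyceride lipase, rose from 15.0 ± 3.45 to 199 ± 22.5 CPM, with 43.9 ± 26.4 CPM in dexamethasone and 110 ± 9.20 CPM in estradiol. TFCP2L1, a transcription factor gene on the glucocorticoid target list, stood at 13.0 ± 0.45 CPM in DMSO, 50.4 ± 16.1 with dexamethasone, 29.9 ± 0.21 with estradiol and 99.3 ± 7.79 with both. CYP1A1 fell by 2.62 and BMF fell by 1.36 on the log2 scale, and the kinase gene PLK2 fell from 180 ± 17.8 to 63.5 ± 2.63 CPM.

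The combination changed 311 genes, 210 higher and 101 lower, with 1528 at an unadjusted p under 0.05. Of these, 96 had been called with neither hormone alone (45 higher, 51 lower). For these 96 the interaction was called for 0 by edgeR, DESeq2 or limma-voom and had an unadjusted p under 0.05 for 12, so their response was not shown to differ from the sum of the single effects. Among the 16 genes with the largest changes, 14 kept their call without each library in turn. NTNG1 lost it without combination replicate 1 (adjusted p = 0.0752), and CLDN9 without DMSO replicate 2 or any estradiol or combination library (up to 0.169). The count was 157 without combination replicate 1, 194 without the other combination library, and 325 without dexamethasone replicate 1.

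Glucocorticoid targets again ranked higher with the combination (14 of 43 higher and 2 lower, 17 and 4 adjusted over the list alone; adjusted p = 7.08e-25, and 0.04 with an estimated correlation). So did estrogen targets (16 of 42 higher and 1 lower, 24 and 2 adjusted over the list alone; adjusted p = 5.2e-21, and 0.0582 with an estimated correlation). Ion and water transport genes rose in 4 of 14 cases and fell in 1, also when adjusted over the list alone (adjusted p = 6.36e-08, and 0.0461 with an estimated correlation, which was 0.0516 without dexamethasone replicate 1). SCNN1A rose by 1.40 ± 0.09, SLC9A3R1 by 0.91 ± 0.09 and CA2 by 1.04 ± 0.15. The circadian clock (adjusted p = 0.000978), glycolysis and hypoxia (0.00436), epithelial receptivity (0.0226), steroid receptor (0.0467) and Wnt (0.0483) lists ranked higher, with adjusted p-values of 0.192 to 0.385 with an estimated correlation. In this order 2, 2, 1, 2 and 2 members rose and 0 fell. Adjusted over the list alone 3, 2, 2, 2 and 4 rose, and 1 clock gene and 1 Wnt gene fell. The steroid receptor list had a median log2 fold change of -0.02 against a mean of 0.59, with PGR and GPER1, a membrane estrogen receptor gene, called higher. GPER1 (1.09 ± 0.19) lost its call without DMSO replicate 1 or either combination library (adjusted p up to 0.0714).

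The fourth comparison asked what dexamethasone does in cells that also receive estradiol. TSC22D3 rose from 11.3 ± 0.87 to 66.8 ± 4.63 CPM (log2 fold change 2.56 ± 0.14), PER1 from 17.1 ± 1.74 to 93.1 ± 3.57 CPM (2.45 ± 0.11) and FKBP5 by 1.31 ± 0.11 on the log2 scale. NXPH3, NGFR, STAC2, GMPR, MICALCL and PRR15L rose by between 1.75 and 2.48. ANKRD1, a target of the Hippo pathway, ATHL1 and the cyclin gene CCNL2 fell by between 1.00 and 1.37. PGR (log2 fold change 0.02 ± 0.32) and GREB1 (0.15 ± 0.28) were not called.

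Here 39 genes changed, 34 higher and 5 lower, with 904 at an unadjusted p under 0.05. DESeq2 called 68 genes, and a fit of only the 4 libraries called 151, 71 higher and 80 lower. The count fell to 10 without estradiol replicate 1, 16 without estradiol replicate 2 and 19 without combination replicate 1, and rose to 68 and 63 without DMSO replicates 1 and 2. It was 46 without dexamethasone replicate 1. ANKRD1, ATHL1 and CCNL2 lost their calls without any of the estradiol or combination libraries, with adjusted p-values of up to 0.332, 0.425 and 0.386. Without estradiol replicate 1 the calls of STAC2 (adjusted p = 0.0561), NGFR (0.0754), GMPR and MICALCL were lost, and without replicate 2 those of GMPR (up to 0.0994) and MICALCL. MICALCL was also lost without either combination library (up to 0.291). Of the glucocorticoid targets, 10 of 43 rose and 0 fell, or 18 and 1 adjusted over the list alone (adjusted p = 4.37e-54, and 0.00939 with an estimated correlation). SCNN1A rose by 1.23 ± 0.09 and NFKBIA by 1.13 ± 0.10. Of 42 estrogen targets 0 rose and 1 fell, the same count as adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 1 called by DESeq2. That list did not pass (adjusted p = 0.792), and its median (0.01) and mean (0.02) were above 0 while the test pointed lower. Ribosome biogenesis genes ranked lower (adjusted p = 1.5e-07), and circadian clock (0.00612) and unfolded protein response genes (0.0414) higher, all with an adjusted p of 0.47 with an estimated correlation. PER1 was the clock gene called, with 1 gene in each direction adjusted over the list alone. Of 25 ribosome biogenesis and 19 unfolded protein response genes 0 were called by edgeR, DESeq2, limma-voom or adjusted over the list alone, and 9 and 1 had an unadjusted p under 0.05. The unfolded protein response list did not pass without dexamethasone replicate 1 (adjusted p = 0.0528).

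The fifth comparison asked what estradiol does in cells that also receive dexamethasone. PGR rose from 5.69 ± 4.55 to 36.9 ± 0.59 CPM (log2 fold change 2.67 ± 0.37), and RBM24, NPPC, ALPI and DHRS3 rose by between 2.70 and 3.10. RGS10, a regulator of G protein signalling, rose by 2.30 ± 0.15 and the kinase gene PIM1 by 2.20 ± 0.20. The genes with the largest falls included several that dexamethasone alone had raised. Both comparisons use the same dexamethasone libraries, so a chance high value in these gives a rise in the first and a fall here. LEFTY1 fell from 22.6 ± 5.41 to 3.39 ± 0.15 CPM and STAC2 from 19.4 ± 1.33 to 5.18 ± 0.0425 CPM. TSC22D3 fell by 1.01 and PER1 by 0.45 on the log2 scale. FAM107A, HIF3A, GABRP and LMO3 fell by between 1.60 and 1.89.

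In all, 379 genes changed, 117 upward and 262 downward, and 2371 had an unadjusted p under 0.05. The number of calls rested on single libraries: 89 without combination replicate 1, 90 without dexamethasone replicate 2 and 100 without the other combination library. Without dexamethasone replicate 1, the library with higher estrogen-induced genes, 437 genes changed, 189 upward and 248 downward, and 279 of the 379 were among them. PER1 lost its call without any of the dexamethasone or combination libraries (adjusted p up to 0.316).

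Of 43 glucocorticoid targets, 2 rose and 10 fell when estradiol was added to dexamethasone, or 5 and 14 adjusted over the list alone. CDKN1C, a cyclin-dependent kinase inhibitor, fell by 1.49, PRR15L fell by 1.04 and DDIT4 fell by 1.01 on the log2 scale. The list ranked lower (adjusted p = 0.000159, and 0.445 with an estimated correlation). Of 42 estrogen targets, 15 rose and 2 fell, or 18 and 5 adjusted over the list alone (adjusted p = 6.8e-08, and 0.445 with an estimated correlation). The estrogen targets had an adjusted p of 2.25e-13 without dexamethasone replicate 1, and 0.295 with an estimated correlation. Mesenchymal and actin genes ranked lower (4 of 22 fell, or 6 with 1 higher adjusted over the list alone; adjusted p = 0.000415, and 0.445 with an estimated correlation), namely the Hippo pathway targets CTGF, CYR61 and ANKRD1 and the growth factor gene TGFB2. Epithelial junction and keratin genes also ranked lower (3 of 19 fell, KRT80, KRT23 and JUP, or 7 adjusted over the list alone; adjusted p = 0.000159, and 0.445 with an estimated correlation). Without dexamethasone replicate 2 the calls of CTGF (adjusted p up to 0.0801), CYR61 (0.0707), ANKRD1 (0.164), KRT80 (0.0574), KRT23 (0.225) and JUP (0.348) were lost, and without combination replicate 1 all of these but KRT80. ANKRD1, KRT23 and JUP were also lost without the other combination library, KRT23 and JUP without either estradiol library and KRT23 without dexamethasone replicate 1. Ribosome biogenesis genes ranked higher (adjusted p = 0.0123, and 0.649 with an estimated correlation), with 0 of 25 called by edgeR, DESeq2, limma-voom or adjusted over the list alone and 7 at an unadjusted p under 0.05.

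**Figure D3:**
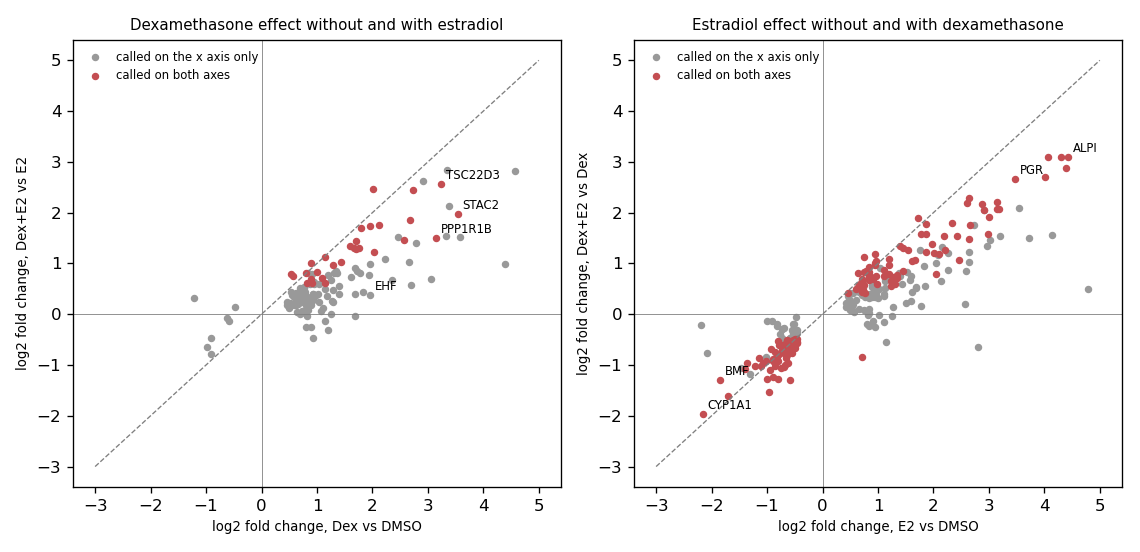
Left, log2 fold change of each gene called with dexamethasone alone (x axis) against its change with dexamethasone in the presence of estradiol (y axis), and right, the same for estradiol without and with dexamethasone. Red points are genes called on both axes, grey points on the x axis only, the dashed line marks equal effects and POTEF is left out; of the 129 genes raised by dexamethasone, 120 are also above 0 with estradiol, at a median of 0.50 against 1.03.

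Both hormone effects were then compared without and with the other hormone, over contrasts that share no library. Of the 129 genes raised by dexamethasone alone, 29 were also raised in the presence of estradiol, where independent lists would share 0.309. Across the 14201 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.222 and a Spearman correlation of 0.228. The 29 shared genes fell to 10 without estradiol replicate 1, 14 without estradiol replicate 2, and 16 and 19 without combination replicate 1 and the other combination library. There were again 29 without dexamethasone replicate 1. For estradiol, 77 genes rose and 54 fell in both contrasts, against 1.39 and 1.61 for independent lists, with a Pearson correlation of 0.401 and a Spearman correlation of 0.405. These 131 genes became 49 and 41 without estradiol replicates 1 and 2, 39 and 47 without combination replicate 1 and the other combination library, 54 without dexamethasone replicate 2 and 169 without dexamethasone replicate 1. The 169 genes raised by estradiol alone had a median log2 fold change of 1.17, and of 0.70 in the presence of dexamethasone, and 158 had the same sign. The 87 genes lowered by estradiol had medians of -0.70 and -0.61, and 86 had the same sign. Because the genes were chosen on the first value of each pair, that value tends to be the larger. The estradiol effect with dexamethasone is also measured against dexamethasone replicate 1. At 204 genes raised by estradiol in a fit of the DMSO and estradiol libraries alone, that library stood above DMSO by a median log2 difference of 0.549. For replicate 2 this was 0.074. The higher level in replicate 1 lowers the second value for genes that estradiol raises.

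The interaction test asked whether the combination departed from the sum of both single effects on the log2 scale. It was called for 3 genes, POTEF upward and PPP1R1B and EHF downward. An unadjusted p under 0.05 was found for 733 of 14201 genes, about as many as that threshold passes when no gene changes. PPP1R1B stood at 7.47 ± 0.94 CPM in DMSO, 65.8 ± 3.22 with dexamethasone, 9.65 ± 0.905 with estradiol and 27.3 ± 2.93 with both, an interaction of -1.64 ± 0.19 (adjusted p = 0.0231). EHF, an epithelial transcription factor gene, stood at 8.35 ± 1.63, 32.3 ± 0.94, 13.7 ± 0.21 and 17.9 ± 1.73 CPM in the same order, an interaction of -1.57 ± 0.20 (adjusted p = 0.0462). TSC22D3 (-0.68 ± 0.20), PER1 (-0.29 ± 0.15), PGR (-0.80 ± 0.55) and GREB1 (-0.60 ± 0.43) were not called. DESeq2 called 13 genes. The count was 10 without dexamethasone replicate 2, 5 without DMSO replicate 2, 1 without either estradiol library and 2 without dexamethasone replicate 1. PPP1R1B lost its call without dexamethasone replicate 1, either estradiol library or the combination library without a number (adjusted p up to 0.331). EHF lost it without dexamethasone replicate 1 or any estradiol or combination library (up to 0.366). With scaling by library size alone 50.0% of the calls were upward, 1 in each direction, against 33.3% of the 3 genes, and EHF had an adjusted p of 0.0700.

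At the level of groups, the interaction was called for 0 members of each of the following lists by edgeR and limma-voom. Of the glucocorticoid targets 10 had an unadjusted p under 0.05 and DESeq2 called 1, and of the estrogen targets 9 and 1. Of the ion and water transport genes these were 7 and 1, of the mesenchymal and actin genes 5 and 0, of the decidualization genes 3 and 0, and of the ribosome biogenesis genes 0 and 0. Adjusted over the list alone, 2 glucocorticoid targets, 1 estrogen target, 6 transport genes, 3 mesenchymal genes, 2 decidualization genes and 0 ribosome biogenesis genes were lower. In the camera test the ion and water transport list (adjusted p = 9.31e-05), the mesenchymal and actin list (9.31e-05), the estrogen targets (0.000439), the decidualization list (0.00614), the glucocorticoid targets (0.00695) and the ribosome biogenesis list (0.0494) had interactions below those of other genes. With an estimated correlation these 6 had adjusted p-values between 0.223 and 0.739. The estrogen targets (adjusted p = 0.217) and the ribosome biogenesis list (0.715) did not pass without dexamethasone replicate 1, while the epithelial junction list did (0.0169, lower, and adjusted p = 0.584 with an estimated correlation).

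Both single responses were also compared with each other. They share the DMSO libraries, so chance values in these raise any overlap. Of the genes called with dexamethasone and with estradiol, 25 rose with both, 1 (POTEF) fell with both and 7 rose with dexamethasone and fell with estradiol. Independent lists of these sizes would share 1.54, 0.049 and 0.79. In 20 simulations of unchanged groups with a shared, also simulated, DMSO group, a mean of 1.3 genes were called for dexamethasone and 0.15 for both hormones. With so few calls an overlap near 0 was fixed in advance, so it gives no scale for the overlap seen. The fold changes had a Pearson correlation of 0.325 across genes, against 0.498 in the simulations, and a covariance of 0.0468 against 0.0286. Their Spearman correlation was 0.0867, which was not computed in the simulations. The 2 DMSO libraries cannot be split into parts of 2 libraries each, so part of the excess may come from the shared controls. Dexamethasone replicate 1 also stood above replicate 2 at 180 of 204 genes that estradiol raised in a fit of the DMSO and estradiol libraries alone. Part of the genes that rose with both hormones may therefore come from that library. The 33 shared genes became 61 without dexamethasone replicate 2 and 22 without dexamethasone replicate 1. They became 21 and 14 without DMSO replicates 1 and 2, 11 and 8 without estradiol replicates 1 and 2, and 19 without either combination library.

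Of the 26 lists tested, 12 passed in none of the 6 comparisons. Their smallest adjusted p-values were 0.289 for receptor cofactors and pioneer factors, 0.0512 for steroid metabolism, 0.305 for immediate early genes, 0.0559 for NF-kB targets, 0.095 for interferon-stimulated genes and 0.144 for DNA replication. They were 0.618 for mitosis, 0.321 for cholesterol synthesis, 0.111 for growth factors and their receptors, 0.618 for fibroblast markers, 0.0965 for replication-dependent histones and 0.288 for housekeeping genes. Without dexamethasone replicate 1, 3 of these passed for dexamethasone against DMSO: steroid metabolism (adjusted p = 0.0329, higher), replication-dependent histones (0.000128, lower) and housekeeping genes (0.0336, higher). With an estimated correlation these had adjusted p-values of 0.49, 0.537 and 0.537. The histones then also passed for estradiol with dexamethasone (0.00105, and adjusted p = 0.449 with an estimated correlation) and for the interaction (2.55e-05, and adjusted p = 0.584 with an estimated correlation), both higher. In these fits dexamethasone alone is represented by replicate 2 only, the library in which RNA45S5 took 1.42% of the counts, and the histone HIST1H1E stood there at 10.9 CPM against 21.9 to 30.3 CPM in the other 7 libraries. Of the fixed target genes, TFF1 had 0 counts in every library. PDZK1, which has a near-identical pseudogene, was called in no comparison (log2 fold change 0.50 ± 0.36 with estradiol).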

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

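Of the tests in this part, the one on NR3C1 and the difference for the 43 glucocorticoid targets were chosen after the result was seen, as was the range over single libraries. Each of the 3 genes here was singled out because its response to dexamethasone differed between cells without and with estradiol in edgeR's quasi-likelihood test of the interaction.

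POTEF had an interaction of 6.43 ± 0.37 (adjusted p = 4.08e-05), because it stood at 75.9 and 99.8 CPM in the DMSO libraries and between 0.786 and 2.11 CPM in all 6 treated libraries. POTEF shares a stretch of 1354 bases at 92% identity with ACTB, which stood between 4788 and 6439 CPM, so the POTEF counts may hold ACTB reads. They amounted to 1.58% and 1.63% of those of ACTB in DMSO and to between 0.0122% and 0.0441% in the treated libraries. Whether these reads came from POTEF, from ACTB or from POTEE, which is 99.3% identical over 3536 bases, cannot be told apart, because the counts do not show where reads fell. A response of POTEF to both hormones also stays open and was not tested.

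PPP1R1B had an interaction of -1.64 ± 0.19 (adjusted p = 0.0231) and EHF of -1.57 ± 0.20 (adjusted p = 0.0462), both with a smaller rise with dexamethasone when estradiol was present. They belong to a wider pattern, in which genes chosen for their rise with dexamethasone alone rose less in the presence of estradiol. Choosing genes on the same libraries that are then measured could produce such a pattern, but it remained when these were kept apart. This split does not remove deviations that both libraries of a group share. No genes were chosen on their response with estradiol, so part of the pattern may still come from the choice of genes. The 100 genes with the largest rise in 1 dexamethasone and DMSO pair were measured in the other pair. Per gene, the log2 response with estradiol was below that in the measured pair by a median of 0.525 (95% interval over genes 0.452 to 0.677, 87 of 100 genes). In the reverse split the median of these per-gene differences was 0.501 (0.355 to 0.631, 81 of 100 genes). With single libraries for the response with estradiol the medians were 0.534 to 0.617 and 0.437 to 0.528. The intervals hold no spread between libraries, but the 0.525 was measured with dexamethasone replicate 2 alone, which argues against the higher estrogen-induced genes of replicate 1 as the whole cause. However, the genes for this value were chosen in replicate 1. The interaction calls of PPP1R1B and EHF were lost without replicate 1, as they were without some other libraries. NR3C1 mRNA was not lower in the combination than with dexamethasone (log2 fold change 0.104, interval -0.106 to 0.315). Over all 8 libraries the median difference for the 43 glucocorticoid targets, 28 of which were not called with dexamethasone, was 0.0939 with an interval of -0.025 to 0.276 that includes 0, and an effect of estradiol on the response of other dexamethasone-induced genes stays open as a hypothesis.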

How the results depend on the processing

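The fits without the ribosomal RNA gene, of the 6 numbered libraries without a block, of all 8 libraries with a block, and the list tests without dexamethasone replicate 1 were chosen after seeing the data. For 186 called values of named genes, 3655 recomputed values gave 3140 on the same side of the threshold, 515 that were no longer past it and 0 with the opposite sign; over all 744 named values 153 of 14375 passed only under an alternative. With no low-count filter, which tests more genes, the counts were 253 for dexamethasone, 442 for estradiol, 132 for dexamethasone with estradiol, 658 for estradiol with dexamethasone and 32 for the interaction; the cause was not tested. With only the libraries of both groups in the fit they were 63 for dexamethasone and 151 for dexamethasone with estradiol, and DESeq2 called 68 genes for the latter and 13 for the interaction; the cause was not tested. At an adjusted p under 0.01, a stricter threshold, 66, 110, 181, 20, 110 and 1 genes passed for dexamethasone, estradiol, the combination, dexamethasone with estradiol, estradiol with dexamethasone and the interaction, and 18, 44 and 9 were shared between the dexamethasone effects, the estradiol effects and both single hormones. With an absolute log2 fold change of at least 1, 67, 115, 153 and 127 genes passed for dexamethasone, estradiol, the combination and estradiol with dexamethasone. Leaving out each library in turn gave 78 to 127 genes for dexamethasone, 58 to 298 for estradiol, 157 to 325 for the combination, 10 to 68 for dexamethasone with estradiol, 89 to 488 for estradiol with dexamethasone and 1 to 10 for the interaction. The shared genes ranged over 10 to 38, 39 to 169 and 8 to 61. Of the gene lists, 9, 7, 8, 4, 5 and 6 passed in the order above, against 2, 0, 2, 1, 0 and 0 with an estimated correlation and 2, 2, 4, 1, 2 and 0 with fry, which tests another question. Scaling by other size factors moved the median log2 fold change of all genes by at most 0.00849. In the simulated data 1.5-fold changes, made only in genes above 2 CPM in DMSO, were recovered in 60% of cases for dexamethasone, 50% for estradiol and 12% for the interaction.

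With the replicate number as a block in the 6 numbered libraries, 239 genes were called for dexamethasone, 441 for estradiol and 60 for both. The same 6 libraries without a block gave 106 and 185, so the higher counts came with the block and not with the libraries left out. Of the gene lists 10 and 7 passed with this block, the NF-kB list for dexamethasone among them (adjusted p = 0.0437, and 0.497 with an estimated correlation). With an estimated correlation the glucocorticoid targets had an adjusted p of 0.0743 and the transport list of 0.497 for dexamethasone. A block of all 8 libraries took the second combination column as replicate 2, which rests on elimination and on the spelling of its label. It called 161, 298, 333, 52, 440 and 3 genes in the order above, the interaction genes being the same 3, and 9, 8, 8, 4, 5 and 5 lists passed. With an estimated correlation the transport list then had an adjusted p of 0.151 for dexamethasone and 0.136 for the combination, while the glucocorticoid targets still passed for both (0.00937 and 0.0312). The deviations of replicate 1 correlated at 0.243 between DMSO and dexamethasone, 0.153 between DMSO and estradiol and 0.0493 between dexamethasone and estradiol, and at -0.187, -0.139 and -0.0999 between the combination and these groups in the order DMSO, dexamethasone and estradiol. The negative values would turn positive if the combination libraries were exchanged, and the numbering of these is not settled. Whether the numbers mark pairs therefore stays open, and the main fit has no block.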

Other observations

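Of the tests in this part, those on mixed RNA, on a difference shared with DMSO and on dexamethasone raising estrogen-induced genes, with the sets of genes they use, were chosen after the result was seen. Growth factors and receptor tyrosine kinases moved in both directions with estradiol, with 4 of 25 higher and 2 lower, or 7 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.478). FGFR2, a receptor for fibroblast growth factors, fell from 95.1 ± 2.32 to 43.1 ± 0.0779 CPM, and stood at 86.3 ± 10.6 CPM with dexamethasone and 47.4 ± 2.69 CPM with both hormones. TGFA, a ligand of the EGF receptor, rose from 216 ± 44.8 to 474 ± 7.28 CPM, a call lost without either estradiol library (adjusted p up to 0.129). IGFBP3, a binding protein of insulin-like growth factors, was at 550 ± 147 CPM with dexamethasone and fell to 252 ± 3.64 CPM when estradiol was added.

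Of 12 enzymes of steroid metabolism, HSD11B2, which inactivates cortisol, rose with estradiol from 3.17 ± 0.564 to 9.99 ± 0.987 CPM and CYP1A1 fell (a call lost without estradiol replicate 2, adjusted p = 0.106), the same counts as adjusted over the list alone. The list did not pass (adjusted p = 0.172), and HSD11B2 lost its call without DMSO replicate 2 or either estradiol library (adjusted p up to 0.149). With both hormones HSD11B2 was at 12.4 ± 0.228 CPM (log2 fold change over DMSO 1.97 ± 0.26). Among the steroid receptors, NR3C2, the mineralocorticoid receptor gene, stood at 22.3 ± 0.689 CPM in DMSO and 18.3 ± 0.440 CPM with estradiol, and was not called.

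Dexamethasone replicate 1 stood above replicate 2 at the 204 genes raised by estradiol in a fit of the DMSO and estradiol libraries alone, by a median log2 difference of 0.448 (95% interval over genes 0.381 to 0.524, 180 genes higher), and below it at the 72 genes lowered in that fit, POTEF left out (-0.235, -0.276 to -0.203). The DMSO libraries differed by 0.126 (0.0547 to 0.176) and -0.106 (-0.203 to -0.061) at these genes, whose choice favours DMSO libraries that are alike, by 0.186 (0.139 to 0.261) against 0.458 (0.395 to 0.546) in dexamethasone at the 204 largest fold changes whatever their p, and by 0.00537 (-0.111 to 0.149) against 0.15 (0.000867 to 0.241) at the 42 fixed estrogen targets, where the intervals overlap. Replicate 2 stood at 0.074 (-0.00708 to 0.178) above DMSO against 0.549 (0.459 to 0.662) for replicate 1, so over genes, with 1 pair of libraries in each group, the values argue against a difference shared with DMSO as the whole cause and against an effect of dexamethasone in both libraries. RNA of an estradiol-treated culture mixed into replicate 1 could raise these genes and should give the same share for every gene. Only genes that estradiol raises entered this test. They were the 75 of the 204 with an estradiol mean of at least 5 CPM and at least 2 times replicate 2. A low chance value in replicate 2, the baseline, tends to raise the share. The median share was 31.4% and the mean weighted by precision 23.5%, and most shares lay between 8.94% and 55.1%. The shares varied 2.81 times as much as replicate noise estimated without replicate 1, and 1.45 times as much with noise from all 8 libraries. The latter estimate contains the difference itself and was computed first, the other being adopted after its result was seen. Mixed RNA therefore cannot be told apart from traces of estradiol or another difference between these cultures, which was not tested.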
